A study of Rattus norvegicus with 5 samples.

How the data were processed

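Total RNA of parental INS-1 cells and of 4 clones was hybridised to single-colour rat expression arrays, 1 array per line or clone. The deposited table holds 1 linear signal intensity per probe set and array, as the values themselves show; the software, background correction and detection calls that the authors used are not given in the sources used here. The trimmed mean of the deposited signals, leaving out the lowest and highest 2%, was 1000.24 to 1000.28 on the 5 arrays, so the arrays had already been scaled to a common level and the signals were used as deposited. No detection calls were used, so a dim probe set cannot be separated from background, and array depth can be described only through signal: the median signal per array was 342 to 372.

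Of 15923 probe sets, 57 control probe sets were left out and 15866 were kept. Gene names came from a platform table: 12783 probe sets had 1 gene symbol, 312 had several and 2771 had none, and no gene was named from the latter. Of the 12783, 12748 matched the GRCr8 gene table by gene number, no symbol changed, and 35 kept the platform's symbol. The signal was taken as log2(signal + 21.8), where the offset is the 10th percentile of all positive signals, so fold changes on this scale understate the change of dim genes. Probe sets were tested when their mean log2 level over the 5 arrays was at or above the 40th percentile, which corresponds to a signal of about 194, and 9520 were tested.

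Samples were grouped by their labels into the parental line (1 array), the 2 clones of set 1-1 and the 2 clones of set 5-3, numbered as replicates in the order of the labels; the numbers name the clones and pair nothing. The clones against the parental line were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) with the 4 clones as 1 group, which leaves 3 residual degrees of freedom and assumes that the parental array varies like the clones. The clone sets were compared in a fit with 3 groups and 2 residual degrees of freedom. p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Nothing says that arrays within a set are repeats of a culture beyond being separate clones, so the p-values measure the spread between these clones. For the clone sets they measure only the spread within each set, not that between such sets. The labels do not say whether clones of a set share an origin. If they do, the 4 clones are not independent. Single clones were compared with the parental line without a test, as counts of probe sets at least 2-fold apart.

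Before the data were examined, 25 gene lists, the comparisons, the filter and the rule for naming genes were fixed. Lists with at least 5 tested members (22 of 25) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, using the brightest probe set of each gene. The lists of other hormones, of acinar and ductal markers and of endothelial and leukocyte markers had 4, 2 and 2 tested members and were only described. For each clone, a list's median difference from the parental array was placed among those of 10000 random lists matched on mean signal in 20 bins. The rule named, for the clones against the parental line, up to 12 probe sets each way past the threshold with all 4 clones on the same side, filled where too few passed by those with the largest smallest-of-4 difference; for the clone sets, 8 each way; for each single clone, the 2 each way with the largest gap to the nearest other array; up to 4 members of each list; and a fixed set of beta cell genes. Some genes of that set are not reported here.

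The tests were run on simulated data in which 200 probe sets were changed by known folds. For the clones against the parental line, 2.99%, 37.3% and 92.4% of probe sets changed 2-, 4- and 16-fold were called. False calls numbered 7 among the unchanged ones of the 9520 probe sets. For the clone sets the shares were 8.96%, 80.6% and 98.5%, with 4 false calls. The simulated probe sets varied independently and the parental array varied like the clones, so these rates do not cover genes that move together. Alternatives covered the scaling (median centring, quantile normalization, cyclic loess), an offset 4 times larger or smaller, the filter, the variance model, the choice of probe set, the set test, the fold limit and leaving out each clone in turn. A fit to the 4 clones alone and a signal limit of 500 were added after the data were seen.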

Results

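RNA was profiled from INS-1 cells, a rat insulinoma line that makes and secretes insulin, and from 4 clones derived from it. The clones carry an FRT recombination site, into which a gene of interest can be placed by Flp recombinase, and a tetracycline repressor, which keeps such a gene off until tetracycline is added. The labels of these samples mention no introduced gene. The clone names fall into the sets 1-1 and 5-3, with 2 clones each; what the first part of the name stands for is not given in the labels. Each full clone name is the set followed by a point and a number: in set 1-1, the clone numbered 2 is called replicate 1 and the clone numbered 16 replicate 2. In set 5-3 the clones numbered 14 and 19 are replicates 1 and 2. They are separate clones, and the plots give their full names. The parental line and each clone had 1 array, 5 in all. Signals are on an arbitrary linear scale with a trimmed mean of 1000 on every array, and the number of arrays limits the precision of every value. Of 15866 probe sets, 9520 were bright enough to test, and they covered 6944 genes.

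The first question was how the engineered clones differ from the line they came from. The most separated genes in the 4 clones included Stc1, which encodes the secreted glycoprotein stanniocalcin 1. Stc1 read 492 in the parental line and 3034 ± 1161 in the clones (SD, n = 4), a fitted difference of 5.64-fold with an SE of 0.46 on the log2 scale; its other probe set gave a log2 difference of 1.95. Runx1, a transcription factor, read 151.4 in the parental line and 1306 ± 535 in the clones (n = 4), and the insulin-like growth factor receptor gene Igf1r read 423.1 and 1707 ± 496. Fbp1, the gluconeogenic enzyme fructose-1,6-bisphosphatase, varied little between clones, with 453.4 in the parental line and 1469 ± 114 in the clones. Among the genes with lower signal in all 4 clones, Ramp1, a partner protein of calcitonin-type receptors, read 1361 in the parental line and 227 ± 58.5 in the clones, and Adora2b, an adenosine receptor, read 4182 and 780 ± 322. The related genes Tmem176b and Tmem176a read 1182 and 1044 in the parental line against 207 ± 74.2 and 295 ± 31.9 in the clones.

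None of these differences passed the test. limma, with Benjamini-Hochberg adjustment, called 0 probe sets higher and 0 lower in the clones at the 0.05 threshold; the lowest adjusted p was 0.887 and 349 probe sets had an unadjusted p under 0.05, where 476 would be expected by chance. A fit with the clone sets as separate groups also called 0, with 632 at an unadjusted p under 0.05. With a single parental array, a simulated 4-fold change was recovered for 37.3% of 67 changed probe sets and a 16-fold change for 92.4% of 66. All 4 clones lay on the same side of the parental array for 38.1% of probe sets, against 40% expected for 5 exchangeable arrays. In all 4 clones 21 probe sets were at least 2-fold higher and 41 at least 2-fold lower, a total of 62. Single clones set apart from all other arrays gave 33 and 70 in 1-1 replicates 1 and 2, and 130 and 58 in 5-3 replicates 1 and 2. By this count the parental array did not stand apart more than a clone. The other named genes with higher signal in every clone were Gcsh, Ackr3, Rai14, Ckmt2, Junb, C5h1orf210, Zfp703 and Phlda1, with fitted folds from 2.34 for C5h1orf210 to 5.54 for Gcsh. Those with lower signal were Crp, Kctd12, Gabrd, Mpv17l, Col9a1, Hpgd, Kcnma1 and Slc26a2, with folds from 2.77 for Slc26a2 to 4.46 for Crp.

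The parental array also stood apart in its added control RNAs. Poly(A) control transcripts that are mixed with the sample before labelling were brighter on it, by 3.56-fold for lys, 1.62-fold for thr, 1.42-fold for trpn, 1.36-fold for phe and 1.35-fold for dap relative to the clones. Hybridisation controls were dimmer on it, at 0.802 of the clones' signal, and lowest on it for 15 of 18 probe sets. The 3′ to 5′ signal ratio of beta-actin, a measure of RNA integrity, was 1.60 in the parental line and 1.49 to 1.73 in the clones. The parental line has a single array, so the handling of that array and the line itself cannot be told apart in any value set against it.

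Genes of cholesterol and fatty acid synthesis formed the group that stood farthest from the parental line. Of 25 measured members, 24 had a lower mean signal in the clones and 22 were lower in all 4, with a median log2 difference of −0.99. Insig1, which controls sterol-dependent processing of the SREBP transcription factors, read 10220 in the parental line and 981 to 6173 in the clones. The desaturase gene Fads1 read 6326 and 765 to 5218, and the sterol reductase gene Dhcr7 read 5053 and 1032 to 2848. The list fell by the camera test with a preset correlation (adjusted p = 2.66e-11 over 22 lists), but its members moved together, and the call was lost with an estimated correlation (adjusted p = 0.496). The depth differed between clones, with medians of −0.70 and −1.87 in 1-1 replicates 1 and 2 and −0.40 and −0.88 in 5-3 replicates 1 and 2. Each lay below all 10000 random lists matched on signal. Random lists draw genes singly, while these members moved together (estimated correlation 0.54), so a list of this kind can fall outside them easily. All 4 medians also subtract the same parental array, so they are not separate tests. Of the members, 0 passed limma's threshold adjusted over all probe sets or adjusted over the list alone, with 4 at an unadjusted p under 0.05.

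**Figure D1:**
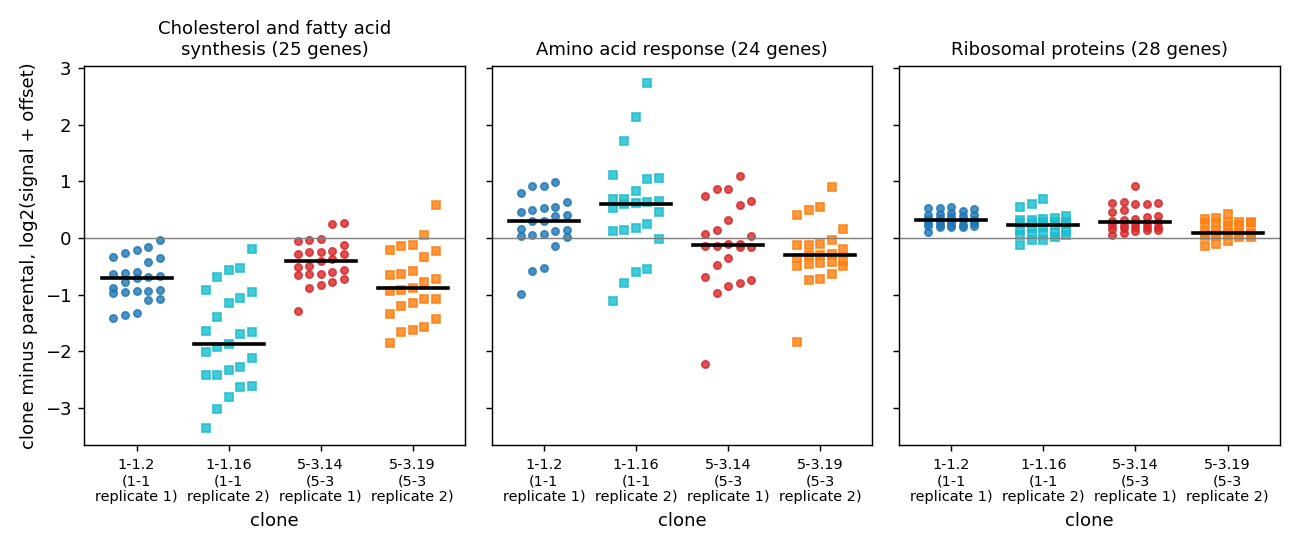
Log2 difference of each clone's array from the parental array, on the log2(signal + offset) scale, for the genes of 3 lists fixed before the data were examined; each point is 1 gene, black bars are list medians and the grey line is the parental level. Cholesterol and fatty acid synthesis genes lay lowest in 1-1 replicate 2 (median −1.87). Amino acid response medians were 0.30 and 0.60 in 1-1 replicates 1 and 2 and −0.12 and −0.30 in 5-3 replicates 1 and 2. Ribosomal protein genes had a clone mean above the parental level for 28 of 28 genes, but for 22 of 28 under cyclic loess scaling.

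Ribosomal protein genes had a higher mean signal in the clones for 28 of 28 members, by a median of 0.23, and 22 were higher in all 4. Examples were Rpl14 (7502 in the parental line, 9131 to 14206 in the clones) and Rps29 (18728, and 23651 to 28427). The list passed camera (adjusted p = 3.95e-09) and not with an estimated correlation (adjusted p = 0.496). The elevation depended on the scaling: 25 of 28 members were higher under quantile normalization and 22 of 28 under cyclic loess, with medians of 0.12. Genes for oxidative stress, glutathione and metallothionein had a higher mean signal in the clones for 19 of 22 members, and 9 were higher in all 4. Among them were the glutathione transferase gene Gsta4 (267.4 against 274 to 2210), Nqo1 (225.7 against 322 to 1017) and the sulfiredoxin gene Srxn1 (676.3 against 822 to 2099). Txnip went the other way, with a log2 difference of −1.24. The list had adjusted p = 0.00112 by camera and 0.496 with an estimated correlation. Without 5-3 replicate 2 the call ended (adjusted p = 0.0625 over a range of 8.17e-05 to 0.608). Cell cycle genes had a higher mean signal for 22 of 32 members, and 11 were higher in all 4 clones. Examples were the replication licensing genes Mcm5 (800.4 against 1086 to 2501) and Mcm6 (2789 against 4047 to 5856), while Cdkn1b was lower (log2 difference −0.85). The list had camera adjusted p = 0.0331, and 0.496 with an estimated correlation. Without 1-1 replicate 1 this call ended too (adjusted p = 0.125 over a range of 0.00819 to 0.608), as it did under cyclic loess and quantile normalization (adjusted p = 0.0670 and 0.0724).

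The remaining lists past the camera threshold were lower in the clones, and each had an adjusted p = 0.496 with an estimated correlation. Hypoxia response genes were lower for 14 of 17 members (median −0.34, adjusted p = 0.00112), led by Ankrd37 (1506 in the parental line, 320 to 643 in the clones) and Mxi1 (2203, and 856 to 1674). Ion channels and pumps that couple stimulation to secretion were lower for 13 of 16 (median −0.55, adjusted p = 0.00112), as for the calcium- and voltage-gated potassium channel gene Kcnma1 (648.1, and 107 to 244), the sodium channel gene Scn3a (2823, and 560 to 2182) and the calcium pump gene Atp2a3 (4860, and 1575 to 2860). Neuronal markers were lower for 15 of 22 (median −0.34, adjusted p = 0.00500), among them Sncb (7400, and 1404 to 3093) and Dcx (2541, and 746 to 1518). Beta cell identity genes were lower for 15 of 19 (median −0.40, adjusted p = 0.00797), including Npy (5552, and 1426 to 4179) and Gad1 (664.4, and 206 to 504). Leaving out 1-1 replicate 2 ended the beta cell call, with adjusted p = 0.0825 over a range of 3.55e-05 to 0.687. The counts in this paragraph are of the mean over the clones. Lower in all 4 clones were 9 of 17 hypoxia, 8 of 16 ion channel, 9 of 22 neuronal and 5 of 19 beta cell members. Of the beta cell members, 10 lay below the parental signal in 1-1 replicate 1 and in 5-3 replicate 1, 18 in 1-1 replicate 2 and 13 in 5-3 replicate 2. All of these lists were set against the parental array, on which the poly(A) controls were brighter (lys 3.56-fold).

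The other 14 tested lists did not pass between the clones and the parental line, with adjusted p from 0.0827 to 0.984, and fry, which tests each list on its own, called 0 of 22. Adjusted over the list alone, limma called 1 member of the cell adhesion list higher, the epithelial adhesion gene Epcam, and 0 members of the other tested lists. Epcam is named after its values were seen. Some of these lists passed under alternatives. Immediate early genes passed without 1-1 replicate 1 (adjusted p = 0.0422) or 5-3 replicate 1 (0.00940), under cyclic loess (0.0461) and under quantile normalization (0.0483), over a range of 0.00940 to 0.789, and the hepatocyte nuclear factor network passed without 5-3 replicate 2 (0.00611, range to 0.842). Interferon and antigen presentation genes passed without 1-1 replicate 1, 1-1 replicate 2 or 5-3 replicate 2 (adjusted p = 0.0254, 0.0431 and 0.0426, range 0.0254 to 0.687). Secretory granule genes passed under cyclic loess and quantile normalization and in the fit with 3 groups (adjusted p = 0.0250, 0.0151 and 0.0151, range 0.0151 to 0.608). For the fibroblast, glycolysis and heat shock lists the median, the mean and the camera direction differed in sign.

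The insulin genes were compared array by array. Ins1 was the brightest probe set on every array and ranged from 34381 to 42217, at a level where a ceiling of the signal can hide a change, so Ins1 was not shown to be stable. Ins2 read 28816 in the parental line and 30224 in 1-1 replicate 1, but 5381 in 1-1 replicate 2, 3953 in 5-3 replicate 1 and 4303 in 5-3 replicate 2, which is 5.34-, 7.26- and 6.67-fold below the parental signal. Over all 4 clones the Ins2 difference was −1.99 ± 1.03 (log2, SE), within the spread between clones (limma adjusted p = 1.00). Between the sets it was −1.62 (limma adjusted p = 0.349), and it passed only in the fit without 1-1 replicate 2, where 1-1 replicate 1 stands alone for its set (adjusted p = 0.00138 over a range of 0.00138 to 0.751). Rat Ins1 and Ins2 are close in sequence, so part of either signal can come from the other gene's transcript. Islet amyloid polypeptide (Iapp) read 27899 in the parental line and 19160 to 33945 in the clones. The beta cell transcription factor Pdx1 read 2830 and 1454 to 2845, and the glucose transporter gene Slc2a2 read 8926 and 4153 to 10531. Hnf4a, a nuclear receptor of the hepatocyte nuclear factor network, read 433.1 in the parental line, 150.2 and 121.4 in the 1-1 clones and 404.4 and 362 in the 5-3 clones; the log2 difference between the clone sets was 1.37 ± 0.27 (SE, limma adjusted p = 0.107). Its other probe set, below the brightness limit, read 186.2 in the parental line, 139.1 and 37.9 in the 1-1 clones and 244.1 and 134.1 in the 5-3 clones, which overlap. Onecut1 was covered only by 2 probe sets below the brightness limit.

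**Figure D2:**
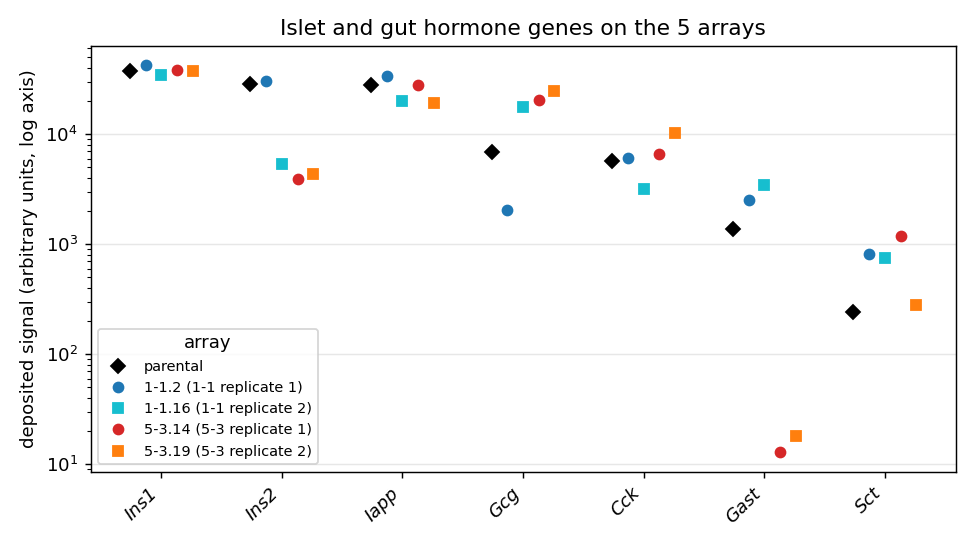
Deposited signal of islet and gut hormone genes on the 5 arrays (log axis, arbitrary units); each point is 1 array, with no replicates within a clone. Ins1, the brightest probe set on every array and so open to a ceiling, lay within 34381 to 42217, Ins2 read 28816 in the parental line, 30224 in 1-1 replicate 1 and 3953 to 5381 in the other clones, and Gast read 12.9 and 18 in the 5-3 clones against 1362 in the parental line.

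Which clone stayed closest to the parental line was examined array by array, without a test. Nr4a3, which encodes a nuclear receptor induced by stimulation, and the retinaldehyde dehydrogenase gene Aldh1a2 set 1-1 replicate 1 apart from all other arrays, higher by at least 3.99- and 3.58-fold. Cpne9 was 7.83-fold lower there, and Lmna read 26.9 against 283 or more elsewhere by 1 probe set, which its other probe set did not show. In 1-1 replicate 2, the stress-induced pseudokinase gene Trib3 and the activin antagonist gene Fst were higher by at least 3.54- and 3.30-fold, and the Wnt inhibitor gene Wif1 and the vesicle trafficking gene Rab3b were lower by 5.54- and 4.61-fold. In 5-3 replicate 1, Gcsh and Slc44a4 were higher by 2.92- and 2.75-fold, and Nell2 and Olfm1 read 16.3 and 56.7 there against at least 290.1 and 546 on the other arrays. In 5-3 replicate 2, another retinaldehyde dehydrogenase gene, Aldh1a1, and the coagulation factor gene F5 were higher by 6.68- and 2.67-fold, and the DNA-sensing adaptor gene Sting1 and Rgs19 read 37.4 and 76.9 against at least 209.5 and 321. For such dim signals the fold depends on the offset: with an offset 4 times larger or smaller the log2 gap was −1.87 or −3.76 for Nell2 and −1.70 or −3.15 for Lmna. Counted over all tested probe sets, 1-1 replicate 1 differed from the parental line by at least 2-fold at 480, 5-3 replicate 2 at 491, 1-1 replicate 2 at 726 and 5-3 replicate 1 at 849. The 1-1 clones differed from each other at 254 probe sets, fewer than any other pair, and the 5-3 clones at 627, whereas pairs across the sets differed at 764 to 1003. Among probe sets with a signal of at least 500 on both arrays, a limit chosen after the data were seen, the counts against the parental line were 196, 193, 340 and 354 in the same order.

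The clone sets differed from each other at single genes, measured against the spread within each set. Fetub, Tff3, Muc13 and Cdh1 were among those higher in the 5-3 clones. Tff3, a trefoil peptide of mucous epithelia, read 28880 ± 2000 in the 5-3 clones and 969 ± 10.96 in the 1-1 clones (SD, n = 2 each), a log2 difference of 4.87 ± 0.18 (SE, limma adjusted p = 0.000383), with the parental line at 7592. Fetub read 2848 ± 412 and 38.7 ± 11.8, with adjusted p = 0.000987 by limma. The vesicular monoamine transporter gene Slc18a1 read 2042 ± 519 and 95.2 ± 34.2, and E-cadherin (Cdh1) 7146 ± 880 and 1305 ± 1.70. The actin bundling gene Espn, the transcription factor gene Tfe3 and Nkain1 were higher in the 5-3 clones by 10.8-, 9.81- and 5.25-fold. Gast, which encodes the peptide hormone gastrin, was near the floor of the array in the 5-3 clones, at 15.5 ± 3.61 against 3007 ± 661 in the 1-1 clones and 1362 in the parental line (limma adjusted p = 0.000499). The 5-3 signals lay below the offset of 21.8, which therefore sets the size of the log2 difference: −6.33 as fitted, and −4.90 or −7.16 with an offset 4 times larger or smaller. Gng3, a G protein gamma subunit gene, read 84.0 ± 64.3 against 3774 ± 1868, and the neurofilament gene Nefl 115 ± 0.778 against 735 ± 206. Marchf7, Rab34, C2cd4b, Ccdc61 and Med13l were lower by 26.0-, 18.1-, 6.20-, 6.08- and 6.05-fold. The folds of the dimmer genes depend on the offset too, with log2 differences of −3.62 or −5.21 for Marchf7 and 2.78 or 3.68 for Espn with a larger or smaller one; the other probe set of Rab34 gave −0.39 on the log2 scale.

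**Figure D3:**
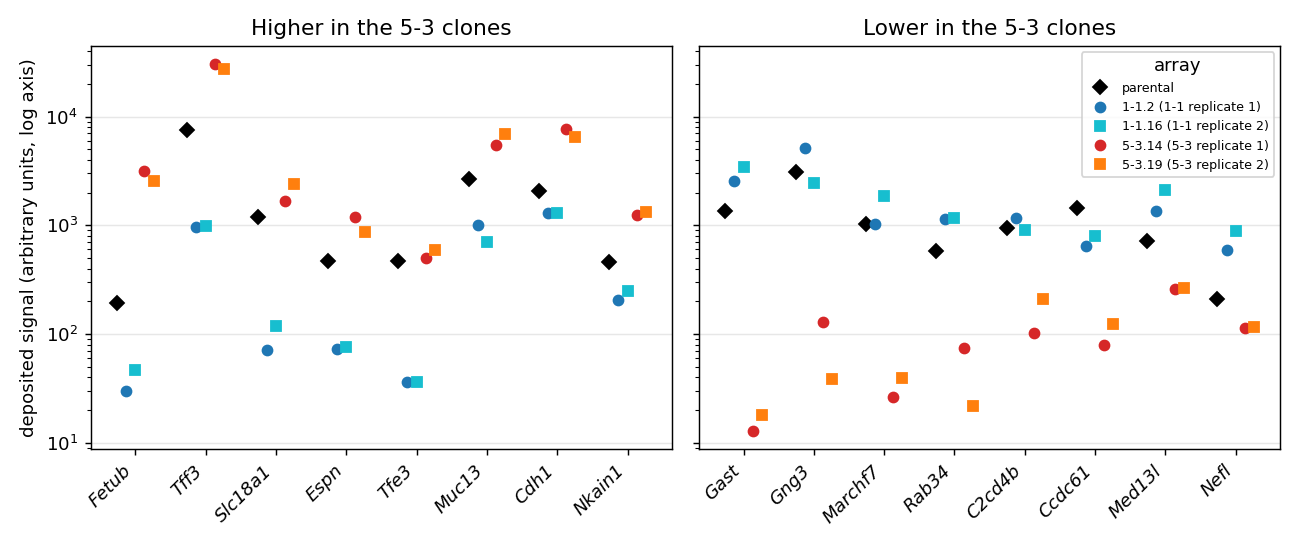
Deposited signal (log axis, arbitrary units) of the 16 named genes that differed between the clone sets, on each of the 5 arrays; each point is 1 array. The parental array lies between the sets for most genes, as for Tff3 at 7592, with the 1-1 clones at 961 and 976 and the 5-3 clones at 30294 and 27465.

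Of the 9520 probe sets tested between the clone sets, 1413 had an unadjusted p under 0.05, where 476 would be expected by chance. In all, limma called 21 probe sets higher and 19 lower in the 5-3 clones. For 32 of the 40 the parental signal lay between the sets. Without 1-1 replicate 1 the counts were 34 and 19, without 5-3 replicate 1 they were 125 and 100, and without 5-3 replicate 2 they were 134 and 195, in fits where the lone clone is assumed to vary like the other groups. Fitted to the 4 clones alone, without the parental array, they were 29 and 25. C2cd4b lost its call without 1-1 replicate 1 (adjusted p = 0.0580 over a range of 0.00149 to 0.124), under cyclic loess (0.0507), without the variance trend (0.0552), with a filter on the highest array (0.0573) and with an offset 4 times smaller (0.0510), and Nefl without 1-1 replicate 2 (adjusted p = 0.0966 over a range of 0.0110 to 0.115). With a filter on the highest array Nefl and Ccdc61 lost theirs too (0.111 and 0.0573; range for Ccdc61 0.00204 to 0.0921). With no brightness filter the counts were 7 and 3, and the calls of Nkain1, Tfe3, C2cd4b, Ccdc61, Gng3, Med13l, Nefl and Rab34 ended.

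Among gene groups, the amino acid response, the ATF4-driven programme that cells use when amino acids are short, was lower in the 5-3 clones for 22 of 24 members (median −0.54, camera adjusted p = 0.000124, and 0.634 with an estimated correlation). For 9 members, all lower, the difference passed limma when adjusted over the list alone, and for 0 over all probe sets, with 12 lower and 2 higher at an unadjusted p under 0.05. Atf5 read 5255 and 5491 in the 1-1 clones and 2362 and 1573 in the 5-3 clones, and Cebpb read 1259 and 2200 against 729 and 743. The Atf5 log2 difference was −1.76 and −1.18 without 5-3 replicate 1 or 2, where a lone clone stands for its set. Genes of the unfolded protein response and ER chaperones were lower for 21 of 25 members (median −0.39, camera adjusted p = 0.00545, and 0.634 with an estimated correlation), among them Sdf2l1 (9900 and 2938 against 4155 and 1157) and Creld2 (7948 and 4299 against 3276 and 2132). Without 1-1 replicate 1 or 5-3 replicate 2 that call ended, with adjusted p = 0.109 and 0.103 over a range of 9.04e-06 to 0.634.

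Cholesterol and fatty acid synthesis genes were higher in the 5-3 clones for 23 of 25 members (median 0.58, camera adjusted p = 0.00018, and 0.634 with an estimated correlation), as for Mvd (278.5 and 85.2 against 866 and 618) and the squalene epoxidase gene Sqle (2223 and 935 against 4469 and 3750). That call rested on 1-1 replicate 2: without it the mean difference was 0.12, with adjusted p = 0.272 over a range of 4.52e-16 to 0.634. Without 1-1 replicate 1, where replicate 2 alone stands for the 1-1 set, the log2 difference was 2.82 for Mvd and 2.10 for Sqle. Without 5-3 replicate 2 it was 2.31 for Mvd. Oxidative stress and glutathione genes were higher for 15 of 22 members (camera adjusted p = 0.00151, and 0.634 with an estimated correlation), led by the glutathione transferase genes Gsta4 (274 and 584 against 1000 and 2210) and Gstm1 (433 and 432 against 1214 and 1953). The difference passed when adjusted over the list alone for 4, Gsta4, Gstm1, Nqo1 and Prdx2, and for 0 over all probe sets, with 6 at an unadjusted p under 0.05. Without 5-3 replicate 2 the list's adjusted p = 0.0787 over a range of 0.000233 to 0.634. Gstm1 passed limma singly under median centring (adjusted p = 0.0438, highest under any alternative 0.149). With a lone clone standing for the 5-3 set, the log2 difference was 2.40 for Gsta4 without replicate 1 and 1.44 for Nqo1 without replicate 2. For Gstm1 it was 2.12 and 1.44 without 5-3 replicate 1 or 2.

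Cplx1 was lower in the 5-3 clones (log2 difference −0.87), but exocytosis genes were higher there for 21 of 26 members (camera adjusted p = 0.0272, and 0.634 with an estimated correlation). Rab3b read 764 and 149 against 2948 and 3012, and the calcium sensor gene Syt7 398 and 519 against 894 and 678. That list's call ended without 1-1 replicate 1 and without 5-3 replicate 1, where its mean log2 difference was 0.28 and 0.26. Without 1-1 replicate 1 or 5-3 replicate 2, where a lone clone stands for a set, the Rab3b log2 difference was 4.14 and 3.02. The other 17 lists did not pass between the sets, with adjusted p from 0.168 to 0.956. In the cholesterol, unfolded protein and exocytosis lists 0 members passed limma over all probe sets or adjusted over the list alone, with 6 higher and 0 lower, 2 higher and 6 lower, and 5 higher and 2 lower, in that order, at an unadjusted p under 0.05. With all arrays 5 lists passed, with 8 without 1-1 replicate 1 and 3 without 5-3 replicate 2. Some lists passed only with 1 array left out. Where that array was a clone, a lone clone stood for a set, so only mean log2 differences are given. Without 1-1 replicate 1 they were 0.44 for beta cell identity, −0.56 for immediate early and 0.31 for ion channel genes. In the same fit they were 0.39 for secretory granule and 0.86 for fibroblast genes. Without 1-1 replicate 2 it was 0.43 for cell adhesion genes, and without 5-3 replicate 1 it was 0.69 for the hepatocyte nuclear factor network. Fibroblast genes also passed without the parental array (camera adjusted p = 0.0213). The highest adjusted p of these lists under any alternative lay between 0.634 and 0.989. fry called 0 of 22 lists in 1 direction and 10 of 22 for change in either direction. It asks whether members differ at all, not whether they differ more than other genes. With 1413 of 9520 probe sets at an unadjusted p under 0.05, the 10 calls do not single out these lists.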

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

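The tests of control signals, of distances between arrays and of the insulin genes in this part were chosen after the values were seen; the tests under cyclic loess scaling were chosen before their results were seen.

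Added control RNAs, which no comparison uses, stood apart on the parental array: the poly(A) controls were brighter there than on the clones' arrays by 3.56-fold (lys), 1.62-fold (thr), 1.42-fold (trpn), 1.36-fold (phe) and 1.35-fold (dap). A separate handling of that array is a candidate explanation for the gene lists that were shifted between the parental line and the clones, and it cannot be told apart from the line itself, which has no other array. Level-dependent scaling was tested as another explanation, and under cyclic loess the cholesterol and fatty acid synthesis medians stayed at −0.43 or lower in every clone, below all matched random lists, which argues against it for this list. For the ribosomal protein list the loess medians were 0.10 and 0.23 in 1-1 replicates 1 and 2 and 0.10 and 0.07 in 5-3 replicates 1 and 2, at percentiles of 98.8, 100, 97.52 and 92.69 among matched random lists. By the limit set beforehand 3 of the 4 clones spoke against scaling, but 97.52 lies within the sampling spread of the random lists around that limit, a margin added after the value was seen, so scaling stays open for this list, as does an untested difference between the lines.

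The clone sets differed in gene lists by camera with a preset correlation, though not with an estimated one: the medians of the 5-3 minus 1-1 differences were 0.58 for cholesterol and fatty acid synthesis, −0.54 for the amino acid response, −0.39 for the unfolded protein response and ER chaperones, 0.24 for oxidative stress and 0.18 for exocytosis machinery. The cholesterol difference rested largely on 1-1 replicate 2, without which the mean was 0.12. From 1-1 replicate 1 to 5-3 replicate 1 the median was 0.24, with 21 members higher and 4 lower. From 1-1 replicate 1 to 5-3 replicate 2 it was −0.096, with 12 members higher and 13 lower. Without 1 clone the calls of the unfolded protein response (1-1 replicate 1 or 5-3 replicate 2, 0.109 and 0.103, range 9.04e-06 to 0.634), oxidative stress (5-3 replicate 2, 0.0787, range 0.000233 to 0.634) and exocytosis (1-1 replicate 1 or 5-3 replicate 1, 0.0568 and 0.146, range 0.00630 to 0.634) ended.

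The cholesterol list also lay at different depths within the 1-1 set, since its median in replicate 2 was −1.08 relative to replicate 1, with 24 of 25 members lower. Under cyclic loess the difference was −1.05, which argues against level-dependent scaling. A difference in culture density or sterol supply, or between the clones themselves, stays open, and no biological explanation was tested.

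Among the clones, 1-1 replicate 1 lay far from the others for Ins2, where its gap to the next clone made up 0.849 of the whole range. A label exchanged with the parental sample was examined by the distances between arrays. At least 2-fold apart, 1-1 replicate 1 differed from 1-1 replicate 2 at 254 probe sets and from the parental line at 480. That argues against an exchange only if clones of a set lie nearest each other and handling of the parental array did not enlarge the 480. The labels give neither, and 5-3 replicate 2 lay nearer to the parental line (491) than to its set partner (627). A smaller share of beta cell-like cells in the other clones would lower beta cell genes together. The list without Ins2 had medians of −0.77, −0.06 and −0.19 in 1-1 replicate 2 and 5-3 replicates 1 and 2. Ins2 lay at −2.42, −2.86 and −2.74 there, which argues against such a smaller share as the whole cause. That 0 of 18 members were as low as Ins2 adds little, since Ins2 had the largest difference in its list. Signal shared with Ins1 stays open, because Ins1 varied only 1.23-fold between arrays but was the brightest probe set on each of them, where a ceiling may hide a change. A partial change of cell identity stays open. In 1-1 replicates 1 and 2 and 5-3 replicates 1 and 2, Npy read 4179, 1621, 1664 and 1426, Gad1 504, 206, 227 and 288, and Ero1b 2472, 808, 1079 and 700.3. After Ins2, these members had the largest differences from the parental array. Others did not follow Ins2: in the same order Iapp read 33945, 19870.5, 28102 and 19160, Pdx1 2343, 1454, 2845 and 2185, and Slc2a2 5337.5, 6485, 4153 and 10531. The alpha cell hormone gene Gcg read 2064, 17772, 20550 and 24434. On the parental array Gcg lay above 1-1 replicate 1 and below the other clones, although Ins2 was high there. A clone difference in Ins2 is open too, as untested.

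Other values of 1 clone far from those of the other 3, as shares of the whole range, were Phlda1 (0.868), Aldh1a2 (0.840), Lmna (0.840), Npy (0.857) and Gcg (0.871) in 1-1 replicate 1, Kcnma1 (0.853) and Atp2a3 (0.872) in 1-1 replicate 2, and Olfm1 (0.835) and Rrm1 (0.846) in 5-3 replicate 1. The medians of the ion channel list (0.841) and of the hepatocyte nuclear factor list (0.853) were set apart by 5-3 replicate 2. In all, 12 of 159 values examined lay past Dixon's limit, where chance, at about 5% of groups, gives 7.95, and Aldh1a2, Lmna and Olfm1 had been named for their gap.

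Genes named as list members differed between the sets. They either passed limma's threshold or had both clones of a set above the parental signal and both of the other set below it. These genes had been picked from their lists by that call or by the size of this same difference, so that they differ is no separate support. The 5-3 minus 1-1 log2 differences called were −2.28 for Nefm, 1.79 for Cltrn, 1.61 for Fn1, −2.08 for Ldhb and −2.39 for Ifitm1. Those not past limma's threshold were 1.77 for Pcsk1n, −0.87 for Cplx1, 0.86 for Rph3al, 0.95 for Timp1, 0.84 for Pfkl, −1.29 for Dnajc3, −1.88 for Atf3, −1.47 for Atf5, 1.78 for Gstm1, 1.00 for Prdx2, 0.86 for RT1-S3, −0.82 for Cxcl10 and −1.48 for Gap43. With 1 clone left out, the log2 difference was −2.74 for Atf3 without 1-1 replicate 1 and −1.64 for Dnajc3 without 5-3 replicate 2. Without 5-3 replicate 1 or 2 it was −1.45 and −1.50 for Gap43 and −1.76 and −1.18 for Atf5. In the same fits it was 2.12 and 1.44 for Gstm1 and 1.89 and 1.65 for Pcsk1n. There a lone clone stands for the 5-3 set and the spread comes from the 1-1 pair alone, so calls made there are not taken as support. Gstm1 passed limma under median centring (adjusted p = 0.0438, highest under any alternative 0.149). Pcsk1n passed under median centring (0.0446), with an offset 4 times larger (0.0429) and with the 4 clones alone (0.0493), with a highest value of 0.146.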

How the results depend on the processing

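The fit to the 4 clones alone and the signal limit of 500 were added after the data were seen; the other alternatives, of 23 tried, were fixed beforehand. The counts of 0 probe sets called by limma higher and 0 lower in the clones than in the parental line, with 349 at an unadjusted p under 0.05, were 0 under every alternative run. Between the clone sets, 21 probe sets were higher and 19 lower in the 5-3 clones, against 6 and 6 with a 60th percentile filter, 7 and 3 with no filter, 38 and 32 with median centring and 32 and 32 with an offset 4 times larger. Without the variance trend 13 were higher, and 11 were lower with a filter on the highest array. Leaving out 1 clone gave 29 to 134 higher and 18 to 195 lower. Probe sets at least 2-fold from the parental array numbered 480, 726, 849 and 491 in 1-1 replicates 1 and 2 and 5-3 replicates 1 and 2. In that order they were 1669, 2318, 2307 and 1668 at a 1.5-fold limit, 129, 219, 225 and 115 at a 3-fold limit, 258, 421, 472 and 241 with a 60th percentile filter, 196, 340, 354 and 193 where both signals were at least 500, and 1580, 1828, 2093 and 1563 with no filter. Lists called by camera, 8 against the parental line and 5 between the sets, were 0 and 0 with an estimated correlation and 0 and 0 by fry, and leaving out 1 clone gave 3 to 8 between the sets. Against the parental line 1057 values of single genes kept their direction. As 0 probe sets passed there under any alternative run, their side of the threshold could not change. Between the sets 1024 values kept their direction and their side of the threshold, 33 no longer passed and 31 newly passed. Of list results 521 kept both, 37 no longer passed and 19 newly passed. None of the genes and lists that reversed had passed with all arrays and the main settings. Between the sets, the beta cell identity, cell adhesion, fibroblast, hepatocyte nuclear factor and ion channel lists passed with 1 clone left out and reversed under another alternative. Reversed log2 differences of genes between the sets were 0.012 (cyclic loess) and 0.034 (median centring) for Clu and 0.016 (median centring) and 0 (quantile normalization) for Ins1. Ins1 against the parental line was −0.11 under cyclic loess and 0 under quantile normalization, which ties the brightest values. With 1 clone left out, the ranges against the parental line were −0.18 to 0.39 for Cck, −0.034 to 0.064 for Ins1 and −0.72 to 0.022 for Lcp1. Between the sets they were −0.32 to 0.32 for Clu, −0.12 to 0.22 for Esam, −0.55 to 0.22 for Iapp, −0.17 to 0.13 for Ins1, −0.14 to 0.44 for Krt7, −0.27 to 1.44 for Lcp1, −1.60 to 0.015 for Pfkfb3, −1.42 to 0.58 for Sct, −0.50 to 0.84 for Slc2a2 and −0.28 to 0.81 for Thy1. Reversed mean log2 differences of lists against the parental line with no filter were 0.017 for drug transport, −0.17 for fibroblast genes, −0.22 for glycolysis and −0.090 for heat shock. Under cyclic loess they were −0.016 for glycolysis, −0.012 for heat shock and −0.047 for oxidative phosphorylation, under quantile normalization −0.0022 for glycolysis and −0.038 for oxidative phosphorylation, and with the mean of a gene's probe sets −0.033 for glycolysis, −0.00063 for heat shock and −0.0032 for oxidative phosphorylation. Between the sets they were −0.29 for fibroblast genes, −0.10 for the hepatocyte nuclear factor network, 0.010 for hypoxia and −0.0015 for ion channels with no filter, and −0.083 for fibroblast genes with an offset 4 times larger. With 1 clone left out, list means against the parental line were −0.025 to 0.23 for the amino acid response, −0.031 to 0.078 for exocytosis, −0.088 to 0.092 for glycolysis, −0.012 to 0.046 for heat shock, −0.034 to 0.020 for oxidative phosphorylation and −0.18 to 0.031 for the unfolded protein response. Between the sets they were −0.27 to 0.44 for beta cell identity, −0.055 to 0.43 for cell adhesion, −0.0041 to 0.16 for drug transport, −0.25 to 0.86 for fibroblast genes, −0.070 to 0.11 for heat shock, −0.15 to 0.69 for the hepatocyte nuclear factor network, −0.34 to 0.16 for interferon, −0.013 to 0.34 for ion channels, −0.27 to 0.018 for p53 targets and −0.14 to 0.061 for ribosomal proteins. Counts under another fold limit or filter differ by construction; for the other changes the cause was not tested. A probe set that an alternative's filter removes has no value there. No paired analysis was possible because the replicate numbers only name the clones. Without detection calls, signals near the offset cannot be set against background, and differences of dim probe sets can depend on the offset: of 115 values of genes that set 1 clone apart, the 7 that moved were of Lmna, Nell2, Olfm1, Rgs19 and Sting1 with another offset.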

Other observations

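The tests on lone arrays, on other splits of the clones and on the scaling behind the nearest clone, and the fit to the 4 clones alone, were chosen after the values were seen; the limma comparisons of the clone sets and their other alternatives were fixed beforehand.

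Hormone genes other than insulin varied widely between the arrays. Glucagon (Gcg), the hormone of alpha cells, read 6875 in the parental line, 2064 and 17772 in 1-1 replicates 1 and 2 and 20550 and 24434 in 5-3 replicates 1 and 2. With 5 arrays no correlation with Ins2 was computed. Between the sets Gcg did not pass limma (adjusted p = 0.382). Without 1-1 replicate 2, where replicate 1 alone stands for the 1-1 set, its log2 difference was 3.43. Cholecystokinin (Cck) read 5689 in the parental line and 3178 to 10280 in the clones, and secretin (Sct) 243.8 and 279 to 1176. The acinar, ductal and other pancreatic markers measured were Krt7 (1834 in the parental line, 808 to 1218 in the clones) and Clu (2873, and 2894 to 4511), and those of endothelial cells and leukocytes were Esam (1980, and 1515 to 1995) and Lcp1 (796.7, and 267 to 1324). Pcsk2, the convertase needed to make glucagon, read 9130 in the parental line, 3331 and 1974 in the 1-1 clones and 7512 and 8705 in the 5-3 clones (limma adjusted p = 0.0692 between the sets). Without 1-1 replicate 1, 5-3 replicate 1 or 5-3 replicate 2, its log2 difference between the sets was 2.02, 1.75 and 1.54. In each of these fits a lone clone stands for a set. The convertase inhibitor gene Pcsk1n read 3986 in the parental line, 1836 and 1225 in the 1-1 clones and 4737 and 5627 in the 5-3 clones (adjusted p = 0.0519). In the same 3 fits the Pcsk1n log2 difference was 2.06, 1.89 and 1.65. With both clones in each set, Pcsk1n passed limma under median centring (adjusted p = 0.0446), with an offset 4 times larger (0.0429) and with the 4 clones alone (0.0493). The highest value under any alternative was 0.146.

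Further genes past limma's threshold between the clone sets belonged to lists that did not pass as a whole. The neurofilament gene Nefm read 453 and 491 in the 1-1 clones against 70.9 and 89.8 in the 5-3 clones, where Nefl was lower too. The lactate dehydrogenase gene Ldhb read 2636 and 1872 against 455 and 573, and the interferon-induced gene Ifitm1 464 and 694 against 88.2 and 93.9. Fibronectin (Fn1) read 2314 and 2618 against 8221 and 6953, and the collectrin gene Cltrn 1855 and 2399 against 7062 and 7618. Without 1-1 replicate 1 the calls of Nefm, Ldhb, Fn1 and Cltrn ended (adjusted p = 0.0550, 0.0720, 0.0720 and 0.0580), and without 1-1 replicate 2 those of Nefm and Fn1 (0.0888 and 0.0692). Over all alternatives their adjusted p ranged from 0.00824 to 0.115 for Nefm, 0.00607 to 0.0921 for Ldhb, 0.00914 to 0.0900 for Fn1, 0.0117 to 0.0796 for Cltrn and 0.0127 to 0.157 for Ifitm1, and with no brightness filter all 5 calls ended. The calls of Ldhb, Fn1 and Cltrn also ended without the variance trend (0.0527, 0.0652 and 0.0549), those of Ldhb and Fn1 with a 60th percentile filter (0.0544 and 0.0518), and that of Ifitm1 with a filter on the highest array (0.157). Adjusted over the list alone, differences also passed for 5 neuronal genes (Nefm, Nefl, Gap43, Elavl4 and Stmn2), 4 secretory granule genes (Slc18a1, Pcsk2, Pcsk1n and Ica1), 3 each of glycolysis (Ldhb, Pfkl and Slc16a1) and cell adhesion (Cdh1, Icam1 and Itgb1) and 2 each of the hepatocyte nuclear factor network (Hnf4a and Cebpb) and fibroblast genes (Fn1 and Timp1). With a lone clone standing for the 5-3 set, the log2 difference was −4.44 and −2.13 for Icam1 without replicate 1 or 2. For Slc16a1 it was −2.91 without 5-3 replicate 2. The beta cell (Cltrn), interferon (Ifitm1), hypoxia (P4ha2) and p53 (Sesn1) lists had 1 each. The genes Stmn2, Ica1, P4ha2 and Sesn1 are named after their values were seen. Of all 9520 tested probe sets, 1413 had an unadjusted p under 0.05 between the sets, where 476 would be expected by chance. Some members of a list of any kind can therefore pass when adjusted over that list alone.

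The split of the 4 clones by name gave 40 calls, while the other 2 splits into pairs gave at most 0 by limma, with 343 and 102 probe sets at an unadjusted p under 0.05 against 1413. With 3 splits the share with as many calls, here 1 of 3, cannot fall under 0.05.

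Whether the parental array stands apart more than a clone does was tested by setting each array in turn against the rest. At an unadjusted p under 0.05 by limma, the parental array gave 349 probe sets, within the range of 209 to 775 given by single clones, and 0 passed adjustment for any array. In such fits the difference between the clone sets enters the residual spread; with the sets as separate groups the parental array gave 632, above the 476 expected by chance, and 0 adjusted. The lone-array counts therefore do not settle how far the parental line stands apart.

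The clone 5-3 replicate 2 was nearer to the parental line (491 probe sets at least 2-fold apart) than to its set partner (627). Scaling of the arrays did not account for the order, since under the 3 other scalings the count to the parental line was 491 to 502 and that to the partner 569 to 613.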
